A study of Mus musculus with 8 samples.

How the data were processed

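Total RNA from the cerebral cortex and hippocampus of male mice was hybridised to 1-colour Affymetrix arrays, in 8 samples with 2 per tissue and arm. Per the labels' protocols, RNA was extracted with a NucleoSpin RNA Plus kit and accepted above an integrity number of 7.0, and 250 ng was amplified and labelled with GeneChip WT kits. The series matrix holds log2 values per probe set that the authors had normalized before they deposited them, with RMA named in the submitters' processing notes. The version of RMA, the summary level and whether all 8 arrays were normalized together are not given in the sources used here. The log base is not written in the file; log2 is taken from RMA's usual output and from the range of the values, 1.59 to 19.93. Scanner files were not used here, and no background or detection value was available to set a floor per probe. Stap1, Gh, B4galt1, Vmn2r121, Psg19, Calml4, Olfr180, Vmn1r137, Otx2, Eps8l1, Ndst4 and Spink8 had a compared group mean under the filter limit given below, so their differences are against levels not shown to be above background.

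The table holds 22206 probe sets. GEO's platform annotation gives 1 gene symbol for 19572 and none for 2634, and 0 have several; all 19572 matched a gene of the RefSeq table of assembly GRCm38.p6 by Entrez identifier, and that table was used for names only. Genes with more than 1 probe set numbered 55. Arrays of a group correlated at r of 0.9867 to 0.9915 across probe sets, and no pair was identical, so neither array of a pair is a copy. Each array was taken as 1 sample. These values cannot show that the samples are independent, since technical repeats can differ too. The tag meant for strain holds the sex, so the strain is not stated here.

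Probe sets in the lowest 33.3% by mean over all arrays (below 3.937) were left out, and 14804 were tested. A linear model with 1 mean per tissue and arm was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend; 4 residual and 7.918 prior degrees of freedom). All tests were two-sided, with Benjamini-Hochberg adjustment within each of the comparisons and a threshold of 0.05. The comparisons were exposure in cortex, exposure in hippocampus, the difference between these, and the tissues within each arm. Exposure averaged over both tissues was fitted, for single probe sets, to the means of arrays with 1 arm and number, 2 per arm. The list tests of the average used the 8 single arrays instead. Intervals are 95% intervals from the moderated model, and a fold is the higher over the lower level on the log2 scale.

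Before the data were examined, 20 pathway lists and 16 marker lists were fixed and tested with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene, and adjusted over the 36 lists. Camera with an estimated correlation and fry were run beside it. Some lists share genes: Nr4a2 and Egr3 stand in the immediate early and cortical neuron lists, and Per1 in the immediate early, clock and glucocorticoid lists. Genes were named by a rule fixed in advance. Where at least 10 passed the threshold, those whose arrays did not overlap were named (the 12 largest per direction). Where fewer than 10 passed, all of these were named without regard to overlap. Up to 10 more per direction were then named with unadjusted p under 0.01, at least a 1.5-fold difference and no overlap. For the tissues the 10 largest per direction are named, and for the difference between tissues the 5 smallest p per direction. From each list described, up to 4 members with the smallest p are given, and always Chrna4, Chrna7 and Chrnb2; Fos, Cfap126's single arrays, Folr1 and other array values were picked after they were seen.

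The fits were tested on simulated data with 200 of 14804 probe sets changed. In the cortex comparison 16.5% of 2-fold and 97.5% of 4-fold changes were recovered, and in hippocampus 10.5% and 96.5%. For the difference between tissues the shares were 0% and 74%, and for the average 76.5% and 100%. For the tissues they were 10% and 97.5% in control and 4.5% and 97.5% in exposed arrays. All simulated arrays varied independently, while in the data arrays of 1 arm and number had a consensus correlation of 0.19. The shares for the average may therefore be too high for these data. Wrong calls at 2-fold and 4-fold numbered 7 and 20 in cortex, 2 and 8 in hippocampus, 0 and 17 for the difference, 26 and 12 for the average, and 1 and 13 and 1 and 16 for the tissues. Most of these are a larger share of the calls than the threshold of 0.05 aims at. A list moved by 0.5 on the log2 scale was found in 20 of 20 runs in hippocampus, with 4 calls in 700 tests of other lists. Simulated genes varied independently, while in the data the estimated correlation within a list ran from -0.2 (blood) to 0.89 (choroid plexus). The 4 in 700 is therefore not the rate of false calls for lists whose members vary together.

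Alternatives fixed in advance were no filter or a stricter one, quantile normalization, median centring, eBayes without the trend or robust, array weights, 1 probe set per gene, other thresholds, the arrays of 1 tissue or arm alone, the number as a block, and leaving out each array. After the data were seen, 3 more were added: leaving out both control arrays high in Ttr, leaving genes at least 2-fold different between tissues out of the lists, and testing the lists called in the average without each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.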

Results

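Gene expression was measured on Affymetrix arrays in the cerebral cortex and hippocampus of male mice aged 12 weeks. The mice had received clothianidin, a neonicotinoid insecticide that activates nicotinic acetylcholine receptors, or a vehicle containing 1% DMSO, for 2 weeks. The dose was 50 mg/kg/day, given by the submitters as one without observed adverse effects. There were 8 arrays in 4 groups (control and exposed cortex, control and exposed hippocampus), with 2 arrays in each group. Arrays are named here by tissue, arm and the number in their label, which was 1 or 6 for controls and 3 or 6 for exposed arrays in both tissues. The median log2 value of an array lay between 5.21 and 5.4 over 22206 probe sets, and the number of arrays limits the precision of every comparison. The labels present the arrays of a group as separate samples without stating that they came from separate animals, so p-values measure only the spread between these samples, which may be technical.

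The first comparison asked which transcripts differed between exposed and control cortex. Nr4a2, an orphan nuclear receptor of the immediate early gene class, fell 4.01-fold in exposed cortex (log2 difference -2.0, SE 0.24, 95% interval -2.53 to -1.48, limma adjusted p = 0.037). Its mean log2 value was 13.20 ± 0.28 (SD, n = 2) in control cortex and 11.20 ± 0.19 (SD, n = 2) in exposed cortex, and both exposed arrays lay below both control arrays. The immediate early transcription factors Fosb (log2 difference -1.57, SE 0.37) and Egr4 (-1.52, SE 0.35) were also lower in both exposed arrays but missed the adjusted threshold, each with adjusted p = 0.74. Growth hormone, Gh (-2.26, SE 0.52), and the galactosyltransferase gene B4galt1 (-1.84, SE 0.41) were lower in both exposed arrays too and missed the threshold. Gh measured 5.02 and 6.45 in the control arrays and differed by -1.54 without cortex control 6, and the exposed means of the genes, 3.48 and 3.65, lay under 3.937, the level below which probe sets were left out.

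Other named genes with lower values in both exposed cortex arrays were Prdm8, Coq5, Wdr54, Ppdpf, Fsd1 and Mrpl34, with log2 differences from -1.52 to -1.33. Without cortex control 1 Prdm8 differed by -0.84 and Coq5 by -0.96, and without cortex exposed 6 Wdr54 differed by -0.62 (-2.36 without exposed 3) and Ppdpf by -0.90. Named genes with higher values in both exposed arrays were Gm20172, Stap1, Plekhf2, Smoc1, Klf10, Cdr1os, Ptprb, Leng8, Vmn1r208 and Cd300c2, with differences from 1.13 to 1.43 (Stap1 0.90 without cortex control 1, Cd300c2 0.73 without cortex exposed 3). Among these, the zinc finger factor gene Klf10 differed by 1.24 (SE 0.27), the noncoding transcript Cdr1os by 1.22 (SE 0.24) and Ptprb, a phosphatase gene of blood vessel endothelium, by 1.17 (SE 0.27). All of them missed the adjusted threshold (adjusted p = 0.74). In all, limma called 1 of 14804 probe sets, with 0 higher and 1 lower, while 915 (6.18%) had an unadjusted p under 0.05. The Nr4a2 call was lost when any 1 of the 4 cortex arrays was left out (log2 difference -2.2 to -1.8, adjusted p 0.095 to 0.54). It was also lost without hippocampus exposed 3 or 6 (0.071 and 0.072), with quantile normalization (0.073), without the mean-variance trend (0.23) and without the 2 control arrays high in Ttr, cortex control 6 and hippocampus control 1 (0.075), and over all alternatives the adjusted p was 0.015 to 0.54.

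**Figure D1:**
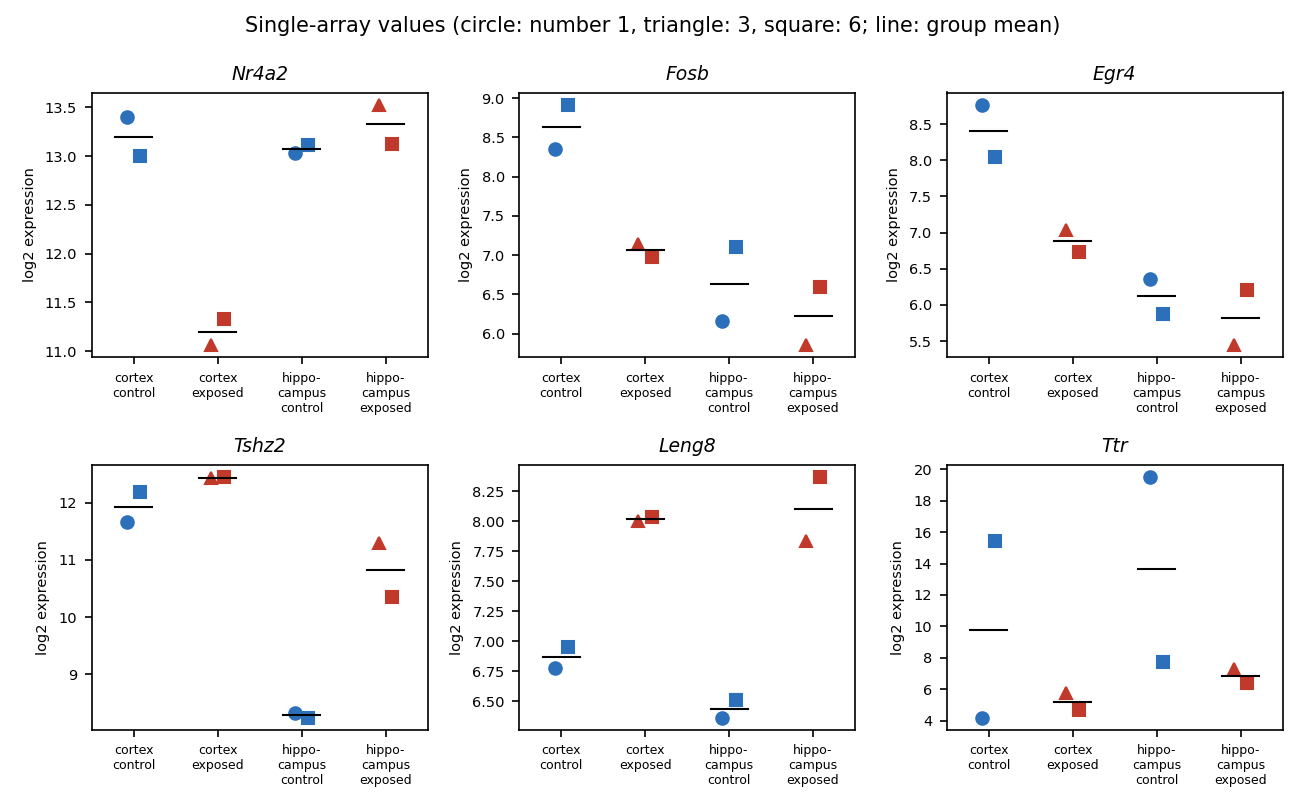
Log2 expression of 6 genes on the y axis in each of the 8 arrays, by tissue and arm on the x axis; points are single arrays (n = 2 per group) and lines are group means. Nr4a2 is at 11.06 and 11.33 in the exposed cortex arrays and at 13.00 or above in the other 6, and Ttr is at 15.41 in cortex control 6 and 19.51 in hippocampus control 1.

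Activity-regulated immediate early genes, which neurons transcribe soon after firing, fell as a list in exposed cortex. Of 33 members tested, 26 were lower and 7 higher, with a median log2 difference of -0.545 (camera adjusted p = 4.5e-05). The list had adjusted p = 0.87 with an estimated correlation, and fry gave adjusted p = 0.74. Besides Nr4a2, Egr4 and Fosb, members with lower values included Arc (-1.06, SE 0.38), Fosl2 (-0.86, SE 0.30) and Nr4a3 (-0.66, SE 0.24), and none of these passed over all genes. Adjusted over the list alone, 3 members passed (Nr4a2, Egr4 and Fosb), against 1 over all genes tested. Here and below, such an adjustment takes no account of the 36 lists tested. It also passed members of lists that were not called, such as 2 hypothalamic neuron markers in hippocampus. In 9 of the 33 immediate early genes both exposed arrays lay below both controls, where chance gives 16.7% of genes. In lists not called this held for 8 of 13 oligodendrocyte, 6 of 13 microglial, 15 of 41 oxidative phosphorylation and 1 of 29 ribosomal genes. The count therefore does not mark out the immediate early list. Fos, Npas4, Egr2, Btg2, Dusp1, Ccn1, Junb and Ier2 were highest in cortex control 1, where Fos measured 11.51 against 8.67 in cortex control 6 and 9.31 and 9.14 in the exposed arrays. Without cortex control 1 the list's median was -0.195 and its adjusted p = 0.74, without cortex control 6 they were -0.965 and 9.6e-15, and without genes at least 2-fold different between the tissues -0.33 and 0.28 (adjusted p 9.6e-15 to 0.87 over all alternatives).

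**Figure D2:**
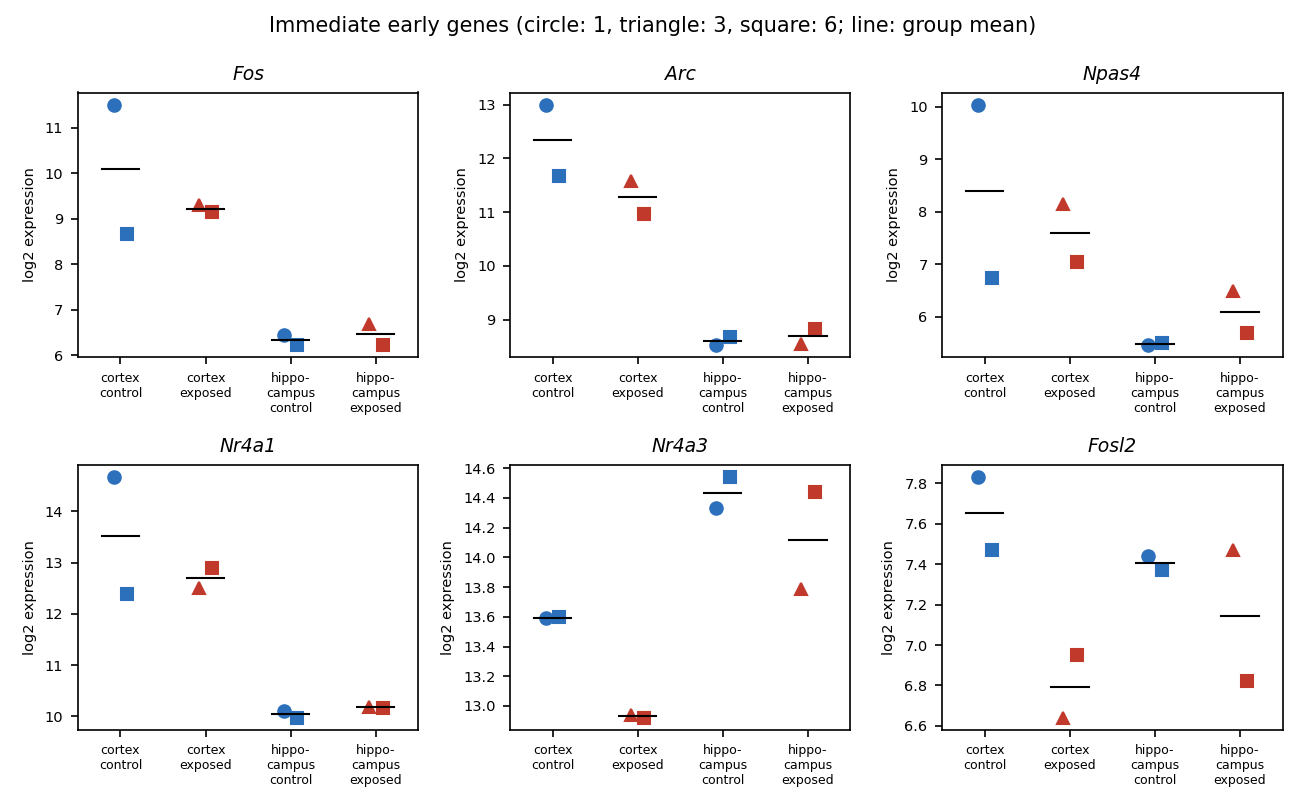
Log2 expression of 6 immediate early genes on the y axis in each of the 8 arrays, by tissue and arm on the x axis; points are single arrays (n = 2 per group) and lines are group means. Fos is at 11.51 in cortex control 1 and 8.67 in cortex control 6, while Nr4a3 is at 13.59 and 13.60 in those arrays and at 12.94 and 12.92 in the exposed ones.

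Of the other lists in cortex, none of 35 passed. Markers of cortical neurons had a median of -0.305 (camera adjusted p = 0.061), with Fezf2 at -0.71 (SE 0.25) and Foxp2 at -0.83 (SE 0.37); Nr4a2 belongs to this list too and was its 1 member called, over all genes and adjusted over the list alone. Microglial markers had a median of -0.29, meningeal and fibroblast markers 0.565 and ribosomal protein genes 0.11, each with adjusted p = 0.097. Markers of oligodendrocytes had a median of -0.215 (adjusted p = 0.12). The median and the mean differed in sign for monoamine signalling, endothelial and thalamic neuron lists in cortex. In hippocampus they did so for cholesterol synthesis, thyroid hormone response, blood and thalamic neuron lists, as for thalamic neurons with a median of -0.0675, a mean of 0.128 and an upward test, and none of these lists was called. Nicotinic receptor subunits, the family to which clothianidin binds, had a median of -0.195 in cortex over the 5 subunits tested (adjusted p = 0.75). Among them Chrna4 differed by -0.09 (SE 0.23; 0.02 with quantile normalization), Chrna7 by -0.79 (SE 0.34; -0.50 without cortex control 1), Chrnb2 by -0.20 (SE 0.31) and Chrna6 by 1.08 (SE 0.29); without cortex control 1 Chrnb2 differed by 0.14, and adjusted over the list alone 1 subunit passed, against 0 over all genes.

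The same question was asked of the hippocampus. Tshz2, a zinc finger transcription factor gene, rose 5.80-fold in exposed hippocampus (log2 difference 2.53, SE 0.31, 95% interval 1.86 to 3.21, limma adjusted p = 0.045). Its mean was 8.29 ± 0.06 (SD, n = 2) in control and 10.82 ± 0.66 (SD, n = 2) in exposed hippocampus, against 11.93 ± 0.36 (SD, n = 2) in control cortex. Higher in both exposed arrays, though missing the threshold, were Ccn2, a matricellular protein gene (2.20, SE 0.63), and Leng8 (1.67, SE 0.28, adjusted p = 0.31). So were the relaxin receptor gene Rxfp1 (1.63, SE 0.31), the G protein regulator gene Rgs17 (1.54, SE 0.31) and the calcium channel subunit gene Cacnb4 (1.25, SE 0.24). Without hippocampus exposed 6, where Ccn2 measured 4.85 against 7.63 in exposed 3, its difference was 3.60 (adjusted p = 0.01), and without exposed 3 it was 0.82 (adjusted p = 0.82). The vesicular glutamate transporter gene Slc17a6 (1.23, SE 0.27) and the neuropeptide gene Nts (1.21, SE 0.31) showed the same pattern, as did Vmn2r121, Vwc2l (0.85 without exposed 3) and Psg19.

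Lower in both exposed hippocampus arrays were Calml4 (-2.30, SE 0.64), 1700007K13Rik, Olfr180, Car12, Dcn, Gh, Stoml3, Gpx8, Ubxn10 and Vmn1r137, with differences from -2.30 to -1.63. Decorin, Dcn, an extracellular matrix gene of fibroblasts, differed by -1.81 (SE 0.48; -1.15 without exposed 6 and -2.47 without exposed 3), and Gh by -1.77 (SE 0.52; -0.98 without control 6). Calml4 measured 7.47 in hippocampus control 1, the array high in Ttr, and 4.80 in control 6. Without control 1 Calml4 differed by -0.97, Car12 by -0.73, Gpx8 by -0.91, Ubxn10 by -0.97 and 1700007K13Rik by -1.42, and without control 6 by -3.64, -2.98, -2.48, -2.33 and -2.62. All of these missed the threshold (adjusted p 0.31 to 0.77). In all, limma called 1 of 14804 probe sets, with 1 higher and 0 lower, while 860 (5.81%) had an unadjusted p under 0.05. The Tshz2 call was lost when any array other than hippocampus control 6 or hippocampus exposed 6 was left out (adjusted p 0.12 to 0.61), as well as with quantile normalization (0.071), with array weights (0.079), without the trend (0.14) and without the arrays high in Ttr (0.26). Over all alternatives its log2 difference was 2.07 to 3.01 and its adjusted p 0.01 to 0.61. Without hippocampus control 6 the count was 56, of which 52 were lower, among them Calml4, Car12, Gpx8 and the choroid plexus genes Folr1, Otx2 and Sostdc1, and without hippocampus exposed 6 it was 2.

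Choroid plexus markers formed the list with the largest shift in hippocampus. All 11 tested members were lower in exposed arrays, with a median log2 difference of -2.74 (camera adjusted p = 1.3e-08; adjusted p = 0.72 with an estimated correlation). The difference came with high values in hippocampus control 1, where Ttr, the transthyretin gene, measured 19.51 against 7.76 in control 6 and 7.27 and 6.39 in the exposed arrays. Folr1 measured 11.55 and 4.43 in those control arrays. Without hippocampus control 1 the list's median was 0.025 (adjusted p = 0.98), and without control 6 it was -5.78 (3.8e-43). The 5 tested ependymal markers, genes of ciliated ventricle lining, also fell (median -0.93, camera adjusted p = 0.00097; adjusted p = 0.72 with an estimated correlation), with Cfap126 at -2.11 (SE 0.80) and Ak7 at -1.56 (SE 0.42). Adjusted over the list alone 3 ependymal genes passed, against 0 over all genes. Cfap126 was at 9.47 in hippocampus control 1 and 5.88 in control 6. Without control 1 Cfap126 differed by -0.32 and Ak7 by -0.90, and without control 6 they passed (-3.91, adjusted p = 0.00032, and -2.23, 0.034). Without control 1 the ependymal median was -0.315 (adjusted p = 0.15; 1.9e-06 to 0.72 over all alternatives), and with no filter it was -0.245 (0.0078).

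The heat shock and unfolded protein response list fell (median -0.217, camera adjusted p = 0.0032; adjusted p = 0.72 with an estimated correlation), with 19 of 28 members lower. The chaperone gene Hspa5 (-1.06, SE 0.19) and the transcription factor gene Xbp1 (-1.22, SE 0.23) were its strongest members, both missing the threshold over all genes (adjusted p = 0.31) and passing when adjusted over the list alone, where 2 passed against 0 over all genes. The list of NRF2 and antioxidant response genes fell as well (median -0.26, 21 of 26 lower, camera adjusted p = 0.011; adjusted p = 0.72 with an estimated correlation), with the catalase gene Cat at -0.82 (SE 0.39; -0.26 without hippocampus control 1) and Gstm1 at -0.50 (SE 0.25; -0.30 without exposed 6). Without hippocampus control 1 the heat shock median was -0.02 (adjusted p = 0.38) and the NRF2 median -0.0075 (0.91); without exposed 6 they were -0.205 (0.099) and -0.03 (0.44), and without control 6 -0.512 and -0.41 (0.00017 for each). In cortex these lists had medians of -0.0875 and -0.177 with adjusted p of 0.19 and 0.18.

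Glutamate signalling, circadian clock and ribosomal protein lists rose in exposed hippocampus. Glutamate signalling genes had a median of 0.235, with 20 of 29 higher (camera adjusted p = 0.0081; adjusted p = 0.72 with an estimated correlation), including Slc17a6 and the NMDA receptor genes Grin2b (0.73, SE 0.30) and Grin2a (0.62, SE 0.28), at 0.32 and 0.20 without hippocampus exposed 6 and 1.15 and 1.04 without exposed 3. Circadian clock genes had a median of 0.165, with 13 of 21 higher (camera adjusted p = 0.0098; adjusted p = 0.72 with an estimated correlation). The clock members with the smallest p were Nr1d2 (0.84, SE 0.22), Bhlhe41 (0.80, SE 0.24), Hlf (0.78, SE 0.28) and Rora (0.68, SE 0.26; 0.40 without control 6). Ribosomal protein genes had a median of 0.22, with 24 of 29 higher (camera adjusted p = 0.011; adjusted p = 0.75 with an estimated correlation), such as Rps19 (0.85, SE 0.37; 0.26 without hippocampus control 1 and 1.45 without control 6). Adjusted over the list alone 1 glutamate gene (Slc17a6) and 1 clock gene (Nr1d2) passed, against 0 over all genes. Without hippocampus control 1 the calls were lost while the medians stayed near their size, at 0.205 for glutamate (adjusted p = 0.093), 0.145 for clock (0.25) and 0.215 for ribosomal genes (0.25). Without exposed 6 the medians were 0.06 (adjusted p = 0.34), 0.04 (0.081) and 0.49 (7e-08), without exposed 3 the clock median was 0.35 and the ribosomal one -0.075 (0.65), and without control 6 the glutamate and clock medians were 0.145 and 0.385.

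Markers of cortical neurons also rose in exposed hippocampus (median 0.145, 11 of 18 higher, camera adjusted p = 0.0056; adjusted p = 0.72 with an estimated correlation), led by Mef2c (0.93, SE 0.21), Ccn2, Rasgrf2 (0.71, SE 0.25; 0.47 without control 6) and Cux2 (0.65, SE 0.29; 0.34 without exposed 3). The 119 probe sets 4- to 8-fold higher in cortex had a median difference of 0.38 in exposed hippocampus, and 82.4% of them were higher. Against the control mean, this median was 0.50 in hippocampus exposed 3 and 0.28 in exposed 6. Adjusted over the list alone 2 cortical markers passed (Mef2c and Ccn2), against 0 over all genes. The marker median was 0.215 without hippocampus control 1 (adjusted p = 0.093), 0.24 without control 6 (0.011), 0.075 without exposed 3 (0.31) and 0.295 without exposed 6 (1.8e-05), and with the lowest 50% of probe sets left out it was 0.03 (0.018). Tshz2, Ccn2, Rgs17, Cacnb4 and Slc17a6 all had higher means in control cortex than in control hippocampus, such as 14.23 against 11.54 for Cacnb4. Without genes at least 2-fold different between tissues the cortical marker median was -0.06 (adjusted p = 0.54), the glutamate median was 0.108 (0.15), the clock median 0.045 (0.40) and the ependymal median -0.335 (0.11). For cortical markers this setting removes by construction the members that differ most between the tissues, so it does not test their rise.

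**Figure D3:**
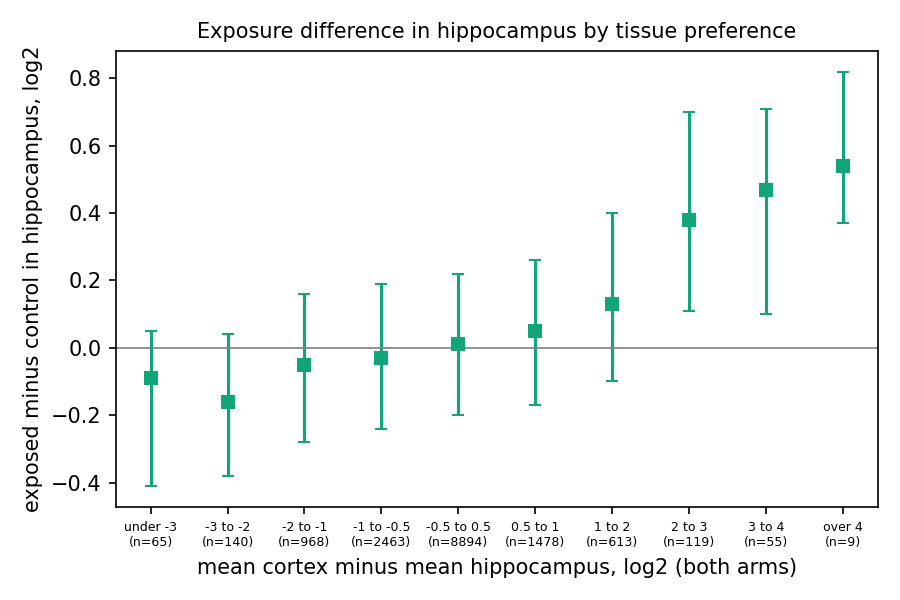
Median log2 difference between exposed and control hippocampus (y axis) for probe sets binned by their log2 difference between cortex and hippocampus over both arms (x axis); squares are medians and bars span the quartiles. The median is -0.16 for the 140 probe sets 4- to 8-fold higher in hippocampus and 0.38 for the 119 probe sets 4- to 8-fold higher in cortex; the bin of genes over 16-fold higher in cortex holds 9 probe sets.

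Nicotinic receptor subunits rose as a list in exposed hippocampus (median 0.41 over 5 tested subunits, camera adjusted p = 0.035; adjusted p = 0.72 with an estimated correlation). Chrna4 differed by 0.88 (SE 0.23), Chrna6 by 0.64 (SE 0.29), Chrna5 by 0.41 (SE 0.29), Chrnb2 by 0.26 (SE 0.31) and Chrna7 by -0.29 (SE 0.34). Adjusted over the list alone 1 subunit passed, against 0 over all genes. With no filter on low values the list's median was 0 (adjusted p = 0.41), with the lowest 50% left out it was 0.26 (0.27), and without any 1 of the 4 hippocampus arrays the call was lost (adjusted p 0.062 to 0.2) while the median was 0.45 to 0.54. Without hippocampus control 1 Chrna7 differed by 0.21, and without exposed 6 Chrnb2 differed by -0.02. The 9 list calls in hippocampus were all lost without hippocampus control 1, where 2 other lists passed (neuropeptides and striatal neuron markers). Without that array the choroid plexus, NRF2 and heat shock medians were near 0 and the ependymal one -0.315, while the nicotinic (0.455), cortical neuron (0.215), glutamate (0.205), clock (0.145) and ribosomal (0.215) medians stayed near or above their size. Fry called 0 of the 36 lists in either tissue (smallest adjusted p 0.14 in cortex and 0.57 in hippocampus), and camera with an estimated correlation also called 0.

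**Figure D4:**
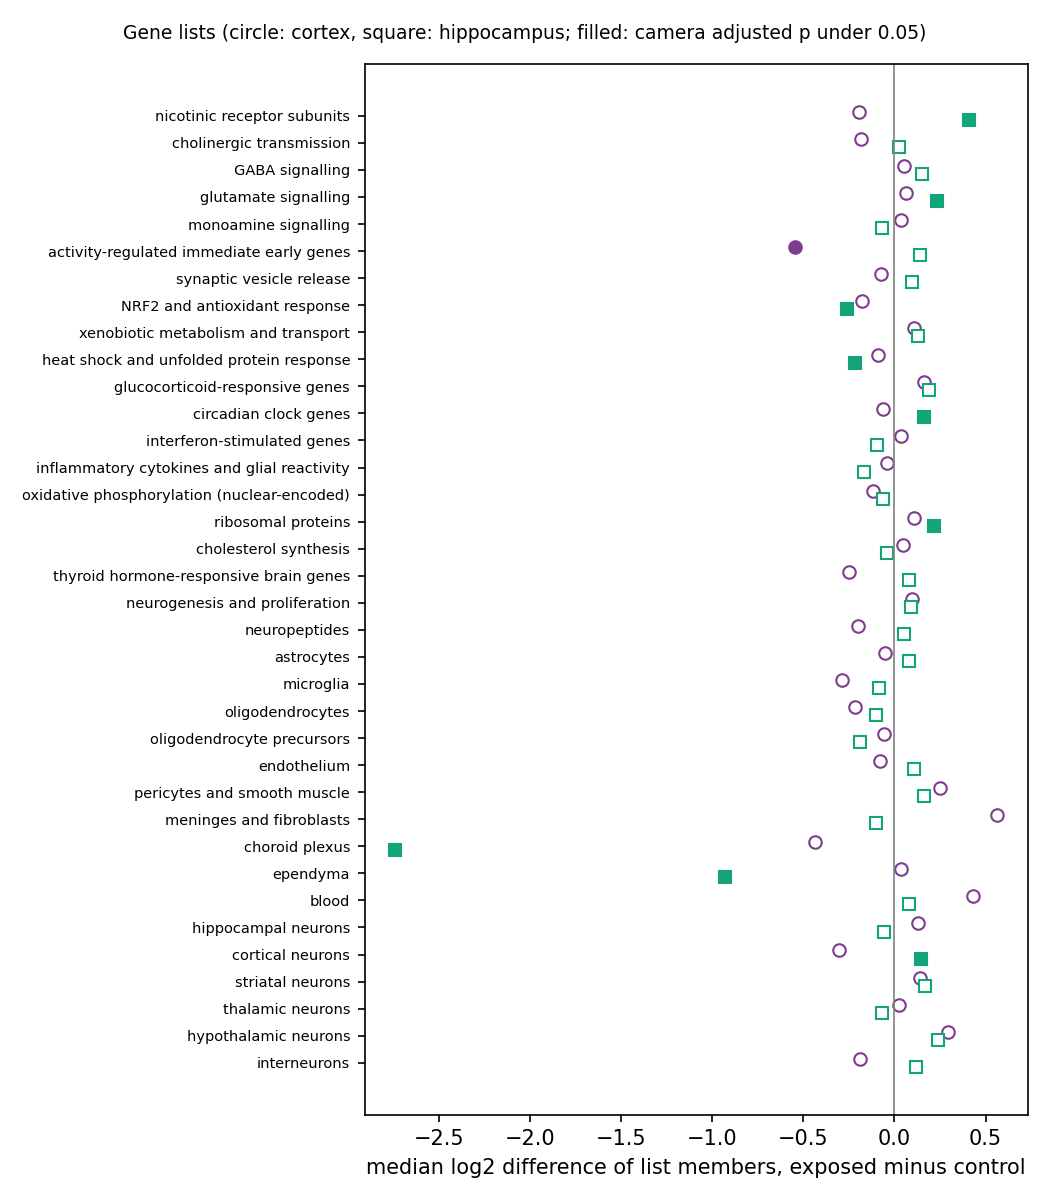
Median log2 difference between exposed and control arrays (x axis) for the 36 gene lists (y axis) in cortex (circles) and hippocampus (squares); filled symbols have a camera adjusted p under 0.05 at the preset correlation. The choroid plexus median is -2.74 in hippocampus, and the immediate early gene median is -0.545 in cortex.

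Averaging the tissues asked which transcripts moved with exposure across both. Arrays of one arm and number were averaged over cortex and hippocampus, giving 2 values per arm. Ttr fell 51.8-fold in these averages (log2 difference -5.70, SE 0.30, limma adjusted p = 6.4e-06). This call rested on 2 control arrays of different numbers, cortex control 6 at 15.41 and hippocampus control 1 at 19.51, while the other 6 arrays lay between 4.17 and 7.76. In a fit of the 8 single arrays Ttr had adjusted p = 0.54. Missing the threshold, Gh was lower (-2.01, SE 0.39, adjusted p = 0.65) and Tshz2 (1.52, SE 0.23, adjusted p = 0.14), Leng8 (1.41, SE 0.23, adjusted p = 0.20) and Ptprb (1.08, SE 0.23, adjusted p = 0.80) were higher.

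Other higher averages were those of Ccn2, Hecw2, Phf20l1, Rmdn1, the neuropeptide gene Vip, Gm20172 and Rgs17 (0.97 to 1.11). Without exposed 3 Ccn2 was at 0.51 (1.70 without exposed 6), and without control 1 Hecw2 was at 0.69 and Rgs17 at 0.63. Lower ones were the choroid plexus genes Folr1, Clic6, Sostdc1 and Kl with Lbp, Eps8l1, 1700007K13Rik, Prdm8 and Ccdc3 (-2.42 to -1.22). Limma called 1 of 14804 probe sets in the average, and 884 had an unadjusted p under 0.05. The count was 26 without control number 6, when Tshz2 (adjusted p = 0.036), Folr1, Clic6, Lbp, Sostdc1, Prdm8 and Kl passed too (Folr1 -3.89, Clic6 -3.63, Lbp -2.91, Sostdc1 -2.81, Kl -2.04). Without control 1 Folr1 was at -0.95, Clic6 at -0.84, Lbp at -1.08, Sostdc1 at -0.64, Prdm8 at -0.76 and Kl at -0.48, all with adjusted p = 1, and 1700007K13Rik was at -0.84 without exposed 6. The count was 3 without control 1, when Gh passed (-2.76, adjusted p = 2e-04; -1.26 and 0.13 without control 6), and 2 without exposed 6. Of the lists, camera called 5: ribosomal proteins rose (median 0.14, adjusted p = 0.009), and choroid plexus (-1.66, 0.00016), NRF2 (-0.18, 0.012), heat shock (-0.108, 0.012) and immediate early genes (-0.213, 0.045) fell. With an estimated correlation the smallest adjusted p = 0.76. Testing these 5 lists without each array, a check added after the data were seen, left none called throughout. The choroid plexus call was lost without hippocampus control 1 (-0.142, adjusted p = 0.32; -3.03 without hippocampus control 6), as were those of NRF2 (-0.0938, 0.25) and heat shock (-0.0725, 0.22; -0.254 without hippocampus control 6). NRF2 and heat shock also lost their calls, with medians near their size, without cortex control 1 (-0.179 and -0.121, adjusted p 0.051 and 0.053) or hippocampus exposed 6 (-0.155 and -0.122, 0.12 and 0.057), and NRF2 without cortex exposed 6 (-0.131, 0.23). Immediate early genes stayed called only without cortex control 6 (-0.572), hippocampus control 1 or hippocampus exposed 6, and without cortex control 1 they were at -0.0125 (0.86). Ribosomal proteins were lost without cortex control 1 (0.03, 0.47), cortex exposed 3 (0.0575, 0.17) or hippocampus exposed 3 (-0.0275, 0.7), and were at 0.308 without hippocampus exposed 6.

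Whether exposure acted differently in the tissues was tested as the hippocampal minus the cortical difference. Among genes with a symbol Nr4a2 had the smallest p, with a hippocampal difference 2.27 above the cortical one (SE 0.34, limma adjusted p = 0.12), which missed the threshold. Other positive values with small unadjusted p were those of Tshz2 (2.02, SE 0.44), Vmn2r121, the DNA demethylase gene Tet2 (1.70, SE 0.40) and Coro6. Negative ones were those of Vmn1r137, Stoml3 (-2.19, SE 0.54), Metap1d, Nubp1 and Ccdc148, and these other genes all had adjusted p = 1. Limma called 0 of 14804 probe sets, and 511 (3.45%) had an unadjusted p under 0.05. Without hippocampus control 6 the count was 30 and Nr4a2 passed (2.30, adjusted p = 0.034), and without hippocampus control 1 it was 1. Camera called 6 of 36 lists, led by cortical neuron markers (median 0.525, adjusted p = 3.2e-06) and immediate early genes (0.62, 1.6e-05). None passed with an estimated correlation (smallest adjusted p = 0.43) or with fry (smallest adjusted p = 0.29).

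Across 14804 probe sets, the cortical and hippocampal exposure differences had Pearson r = 0.211 and Spearman rho = 0.219; genes are not independent replicates, so no p is given. The other ways of pairing the 4 arm and number combinations gave r of 0.176 and 0.0837. Without hippocampus control 1 the real split gave 0.0387, and without hippocampus exposed 6 it gave 0.101.

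The tissues themselves were compared to show the scale of a regional difference. In control mice, the hippocampus had higher levels of the AMPA receptor partner gene Shisa6 (173-fold, log2 difference 7.44, SE 0.36), the heparan sulfate enzyme gene Ndst4 (74.3-fold), the neuropeptide Y receptor gene Npy2r (64.2-fold) and the mineralocorticoid receptor gene Nr3c2 (38.7-fold). Slc29a4, Cabp7, Fibcd1, Tgfb2 and Kl were 33.5- to 43.7-fold higher, with Kl at 12.53 in hippocampus control 1 and 7.38 in control 6 (log2 difference 2.49 without control 1) and not called without cortex control 1 (4.04, adjusted p = 0.12). Spink8 was higher too, but no fold is given because its cortical mean of 3.24 lay under the 3.937 used as a filter. Cortex had higher levels of Dkkl1 (55.7-fold, log2 difference -5.80, SE 0.44), the synaptic organizer gene Cbln2 (42.2-fold), Lamp5 (37.8-fold) and Ccn2 (32-fold), with Cckbr, Rims3, Stx1a, Olfm2 and Kcnh5 at 23.5- to 29.7-fold. Dusp1, at 16.55 in cortex control 1 and 13.83 in control 6, was also higher there (-4.74), by -3.39 without cortex control 1 and -6.11 without control 6. In exposed mice Ndst4, Shisa6, Npy2r, Nr3c2 and Spink8 were again among the genes most above cortex, with the granule cell factor gene Prox1 (35.4-fold), C1ql2 (31.5-fold), St18, Ccnjl and Epha6. On the cortical side Gm765, H2-T23, Cdkn1a and Igfbp6 joined Dkkl1, Cbln2, Stx1a, Lamp5, Kcnh5 and Rims3, with Cdkn1a at -3.71 (-2.47 without hippocampus exposed 6, -4.94 without exposed 3) and Dkkl1 at -5.05 (-4.32 without cortex exposed 3, -5.80 without exposed 6). All named tissue genes passed with limma adjusted p of 0.011 or less.

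Limma called 2620 of 14804 probe sets between the tissues in control mice, 1491 higher in hippocampus and 1129 higher in cortex, and 2143 in exposed mice, 1370 and 773. Of these, 932 were higher in hippocampus and 623 higher in cortex in both arms, against 138 and 59 for independent lists, and 0 went opposite ways. As deposited, the median over all probe sets was 0.10 higher in hippocampus in controls and 0.125 higher in exposed mice; quantile normalization moved it to 0.0116 and 0.005, and median centring to -0.06 and -0.015. The split moved with it, to 1234 and 1278 (control) and 1018 and 978 (exposed) with quantile normalization, and to 1041 and 1496 and 1001 and 1036 with centring. The control count was 1289 without cortex control 1 and 1300 without cortex control 6, and the exposed count was 1074 to 1382 without any 1 of the exposed arrays.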

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

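Of the tests in this part, the 2 on immediate early genes without cortex control 1 as a list and on cortex-enriched genes in cortex were written before their result was seen; the others were chosen after it. The 6 lists here had exposure effects that differed between tissues by camera at the preset correlation, and none of the 6 passed with an estimated correlation (smallest adjusted p = 0.43).

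Choroid plexus markers had a hippocampal effect below the cortical one (median -2.22, adjusted p = 6.7e-05), as did ependymal markers (-1.3, adjusted p = 6.8e-05); without hippocampus control 1 these were 0.745 (adjusted p = 0.20) and -0.635 (adjusted p = 0.076), and without control 6 the choroid plexus value was -5.79. Choroid plexus tissue in the hippocampus control 1 piece is a candidate explanation: without that array the hippocampal marker median was 0.025 (adjusted p = 0.98), and Ttr at 19.51 and Folr1 at 11.55 are abundant choroid plexus transcripts, while Kl, at 7.38 or more in the other hippocampus arrays, may come from the tissue itself. A smaller amount may lie in cortex control 6, where 6 of 10 markers other than Ttr were the highest of the cortex arrays, just over the level set as a sign of it. Among the 10, Kcne2, Otx2 and F5 had control cortex means of 2.91, 3.62 and 3.86. These lie under 3.937, so the order of arrays says little for them. A fall of these transcripts after exposure stays open, since 3 of 11 markers were higher in hippocampus control 6 than in both exposed arrays, where chance gives 33.3%. None of the 11 markers is in another list, and the labels name no sort or gate that would remove this tissue.

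Markers of cortical neurons had a hippocampal effect above the cortical one (median 0.525, adjusted p = 3.2e-06), and this call held when any 1 of the 8 arrays was left out (0.39 to 0.69). The 183 probe sets over 4-fold higher in cortex had a median of -0.17 in exposed cortex (95% bootstrap interval -0.225 to -0.11). In these arrays that argues against a rise of cortex-enriched genes in both tissues. The bootstrap resampled probe sets with the arrays held fixed, so it leaves out the spread between arrays and does not reach beyond them. One uniform share of cortex in the exposed hippocampal pieces was fitted too. The fitted share of 5.82% predicts a median of 0.872 for 64 probe sets over 8-fold higher in cortex. The observed median was 0.482, a gap of -0.39 (interval -0.659 to -0.133, again from resampled probe sets). The prediction takes signals as free of background, which would shrink shifts of probe sets low in hippocampus, and no background value was available. The test therefore cannot decide on such a share, which stays open. The 8-fold limit was set after a first run with a limit of 16-fold and 9 genes had been seen, which pointed the same way. Neighbouring tissue of another makeup and an effect of exposure in hippocampus alone stay open and untested.

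Immediate early genes had a hippocampal effect above the cortical one (median 0.62, adjusted p = 1.6e-05; 0.175 and 0.22 without cortex control 1). High immediate early genes in cortex control 1 alone may account for the list's fall in cortex, since without that array its median was -0.195 (adjusted p = 0.74), though this is just inside the bound of -0.2 set for it. For Nr4a2 the difference was -1.8 without that array, with cortex control 6 at 13.00 against 11.06 and 11.33 in the exposed arrays. In these arrays it was thus not confined to cortex control 1. Nr4a2 was picked as the only gene called, which favours genes alike in both control arrays, and 1 control array remains. The value is therefore a description and decides nothing further. A fall of claustrum and layer 6b markers as large as that of Nr4a2 is argued against in these exposed pieces: 8 such markers other than Nr4a2 had a median of -0.113 in cortex. Its interval, -0.315 to 0.195, gives the spread between markers and not between arrays. Ccn2 (0.01) and Oprk1 (-0.45) had been seen before. The markers ran from -0.45 (Oprk1) to 0.93 (Inpp4b). Their pooled median therefore cannot decide on a smaller loss or on a loss of 1 of the cell types, which stays open. Handling and time of dissection, on which the labels are silent, fewer cells of other cortical layers (Fezf2 -0.71 and Foxp2 -0.83) and an effect of exposure on Nr4a2 stay open and untested.

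Circadian clock genes had a hippocampal effect above the cortical one (median 0.445, adjusted p = 0.006), with the call lost without cortex control 1 (0.25, adjusted p = 0.10), hippocampus control 1 (0.31, 0.19) or hippocampus exposed 6 (0.32, 0.056). Meningeal and fibroblast markers had one below it (-0.605, adjusted p = 0.0046), with the call lost without cortex control 1 (-0.58, 0.073), cortex exposed 3 (-0.15, 0.39), hippocampus control 1 (0.13, 0.25) or hippocampus exposed 6 (0.11, 0.91), and a median of -1.12 without cortex exposed 6 and -1.1 without hippocampus exposed 3.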

How the results depend on the processing

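Leaving out both control arrays high in Ttr, leaving genes at least 2-fold different between tissues out of the lists, and testing the averaged lists without each array were chosen after the data were seen; the other alternatives were not. Where an array is left out, the lone array of its group is assumed to vary like the others, and the cause of a change was not tested except where fewer arrays or genes explain it by construction. Over all alternatives, values of named genes kept their direction and side of the threshold in 2552 cases, lost the threshold in 24, gained it in 20 and reversed in 7. Genes that missed the threshold in both settings count as kept, and genes named for the tissues are included. The exposure calls were less stable: Nr4a2 passed in 9 of 18 alternatives, Tshz2 in 8 of 18 and Ttr in 11 of 13. Each control number holds 1 of the arrays high in Ttr, and no alternative for the average left out both. The Ttr count therefore cannot show that its call holds without them. The counts of changed probe sets (1 in cortex, 1 in hippocampus) were 0 and 0 with quantile normalization and without the trend, 2 and 0 with array weights and with the arrays of the tissue alone, and 3 and 0 without the arrays high in Ttr. At adjusted p under 0.1 the cortex count was 2 and that of the difference between tissues 2. At an unadjusted p under 0.05 with at least 1.5-fold the counts were 828 in cortex, 789 in hippocampus, 511 for the difference between tissues and 542 for the average. Leaving out 1 array in turn gave 0 to 2 in cortex, 0 to 56 in hippocampus, 0 to 30 for the difference between tissues, 1289 to 2532 for the tissues in control mice and 1074 to 2440 in exposed mice; leaving out 1 number gave 1 to 26 for the average. Without both arrays high in Ttr the control tissue count was 1155, and the correlation between tissues 0.016; it was 0.0387 to 0.272 without single arrays.

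Lists called in cortex (1) numbered 2 with no filter, 2 with quantile normalization, 0 with an estimated correlation, 0 with fry, 7 without the arrays high in Ttr, 0 without genes different between tissues, and 0 to 7 without single arrays. In hippocampus (9) they numbered 0 with an estimated correlation, 0 with fry, 2 without the arrays high in Ttr, 5 without genes different between tissues, and 2 to 12 without single arrays. Directions reversed as follows: Chrna4 in cortex was 0.02 with quantile normalization and Chrnb2 in cortex 0.14 without cortex control 1. In hippocampus the choroid plexus median was 0.025, Chrna7 0.21 and Sod3 0.37, each without hippocampus control 1 and again without both arrays high in Ttr. The ribosomal median was -0.075 without hippocampus exposed 3, Chrnb2 -0.02 without hippocampus exposed 6, and the cortical neuron median -0.06 without genes different between tissues. Over single arrays left out, these ranged from -5.78 to 0.025 (choroid plexus), -0.075 to 0.49 (ribosomal), -0.53 to 0.14 (Chrnb2 in cortex), -0.02 to 0.54 (Chrnb2 in hippocampus), -0.78 to 0.21 (Chrna7) and -1.88 to 0.37 (Sod3). Kl between control tissues lost its call without cortex control 1 and with robust eBayes (adjusted p 0.12 and 0.16), as did Cdkn1a between exposed tissues with robust eBayes (0.06).

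Arrays of 1 number share only that number, since the labels do not state a shared mouse; their deviations from group means correlated at -0.000881 in controls and 0.276 in exposed arrays. With the number as a random replicate block (consensus correlation 0.19) the cortex count was 2 and with a fixed block the difference between tissues had 1. The average over 8 arrays had 0 calls with no replicate block and 0 with a random block, where Ttr had adjusted p of 0.54 and 0.79. Arrays give no signal over background here, so low probe sets are limited by noise that could not be measured.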

Other observations

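The genes and probe sets in this part were chosen after their values were seen, and no test was planned for them. Leng8, Ptprb and Gh, genes outside the fixed lists, differed in the same direction in both tissues with no overlap between arms. Leng8 measured 6.36 to 6.95 in the 4 control arrays and 7.84 to 8.37 in the 4 exposed ones. Ptprb measured 6.10 to 6.44 and 7.08 to 7.51. Gh measured 4.42 to 6.45 and 3.36 to 3.53, and its exposed values lie under the filter limit of 3.937. None of these genes passed the adjusted threshold in either tissue with limma. The share of the 14804 probe sets with no overlap between arms in both tissues is not given here. The separation of these genes is therefore a description only.

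Single meningeal and fibroblast genes differed between exposed arrays. Fmod, a fibroblast matrix gene, measured 9.75 in cortex exposed 3 against 7.50 in exposed 6 and 7.67 and 8.02 in the controls, and 9.02 in hippocampus exposed 3 against 4.04, 5.56 and 4.71. Slc22a6 measured 7.20 against 5.89, 6.03 and 5.79 in cortex, and 6.35 against 5.21, 5.62 and 5.59 in hippocampus. Dcn measured 8.67 against 7.13, 7.69 and 7.69 in cortex, but in hippocampus 10.79 in exposed 3 and 9.47 in exposed 6 lay below 11.95 and 11.94 in the controls. Col1a1 was not highest in exposed 3 in either tissue.

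The unnamed probe set TC1700001227.mm.2 had a log2 difference of 7.63 in cortex (SE 1.08, limma adjusted p = 0.0996) and -3.31 in hippocampus (adjusted p = 0.769). It measured 5.78 and 4.01 in the control cortex arrays, 11.53 and 13.52 in the exposed ones, 9.55 and 5.58 in the control hippocampus arrays and 3.34 and 5.18 in the exposed ones. The difference between tissues was -10.94 for it and -3.24 for the unnamed probe set TC0900002778.mm.2, each with adjusted p = 0.0875.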
